A study of Hominidae with 8 samples.

How the data were processed

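Poly-T selected RNA from 2 human breast cancer cell lines was sequenced by the submitters, MDA-MB-231 and MCF-7, each after 0, 1, 4 or 8 h of culture with 4-thiouridine (4sU), with 1 library per line and time, 8 in all. No line and time has a replicate, and the labels state no separate cultures. The deposited values are FPKM, fragments normalised to gene length and to the library's total fragments, made by the authors. HTSeq 0.9.1 and the genome build hg38 are named for these data, per the submitters' processing notes. The aligner, the annotation release, the gene length used and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes, or of near-identical copies, could not be told apart. The table lists 62742 IDs, of which 60617 are Ensembl gene IDs and 2125 are other IDs with a prefix of their own, called non-Ensembl IDs here. It holds no gene symbols and no coordinates, and no annotation was used here, so genes are named by ID only and GC content was not tested. The positions of 4sU-to-C conversions in the reads are not analysed here.

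The values stepped in whole reads. Within a gene the ratio of low FPKM values between libraries gave the relative library totals, and the spacing of the inverse values gave the absolute totals, which came out as whole numbers. For each ID the smallest length that made its reads whole within 1e-06 reads was taken, which succeeded for 31778 of the 31779 IDs above 0. All 175426 values of these IDs are then whole by construction, so the check of the recovery is the sum of reads. The recovered reads added up to between 99.862% and 99.923% of each total, and the cause of the remainder was not tested. For IDs with few reads the true length can be a multiple of the recovered one. The recovered length had a median of 1482 bases among the tested IDs and quartiles of 1043 and 2147. Library totals ranged from 10046314 to 13758980 reads. At 1 FPKM and the median length, counting error alone came to between 22.15% and 25.92% of the value. Reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only.

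Tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, over the 13899 IDs with a mean of at least 1 FPKM in the 8 libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The lines were compared with 4sU time as a factor, so that the 4 time-matched pairs of libraries were the units. Each 4sU time was compared with 0 h with the line as a factor, so that the 2 lines were the units and only changes common to both could be tested. These fits left 3 residual degrees of freedom and take the line-by-time deviations as the spread, which may be technical. A different course in the lines was tested as the interaction of line and hours. It takes a straight line in hours and left 4 residual degrees of freedom. The comparison designs, the alternatives and the rule for named genes were fixed before the data were examined. The 23 gene lists fixed by symbol at that time, 502 entries in all, matched 0 IDs, so neither the tests of gene lists nor the medians of lists in single libraries were made.

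The rule for named genes took those with a symbol, past the threshold and changed in the same direction in every pair, the 12 largest per direction between the lines and the 5 largest per direction for each time, and members of the gene lists. Without symbols the rule could not be met in full. The first 2 IDs per direction in the same order are given for the line difference and for 8 h. Grouping by gene length, by non-Ensembl IDs and by presence of reads was chosen after the data were examined. So were the voom fit on recovered reads, the removal of the length trend by lowess with a span of 0.3, the thinning to the smallest library, the comparisons among labelled times and the fit of all labelled libraries against 0 h. The alternatives fixed beforehand were a pseudocount of 0.1 FPKM, no filter, a minimum mean of 5 FPKM, rescaling by median ratios, no variance trend, no time term for the lines, log2(hours + 1) for the trend and leaving out each library or time-matched pair.

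Each of the 5 tests was tested on simulated reads for 13899 genes, drawn from the real means, totals and spread with 200 genes changed. Each gene had a single mean over all libraries, and the spread came from the fit of the line difference. The simulated reads thus held no shift between 0 h and labelled libraries, and no line difference outside the changed genes. Changes between times were placed at the tested time, and slope differences reached the stated size at 8 h. For the line difference, 22% of the genes changed 2-fold and 83% of those changed 4-fold were recovered, with 6 unchanged genes called. For 1 h against 0 h, 0% and 26% were recovered, with 0 unchanged genes called. For 4 h these shares were 0% and 13% with 3 unchanged genes called, and for 8 h they were 1% and 30% with 0. The trend difference recovered 0% at either size, with 0 unchanged genes called, so a count of 0 in that test does not exclude differences of these sizes. With more genes changed the adjusted threshold is less strict, and the real libraries hold the shift, so these shares need not hold for the real data. Figures were drawn with matplotlib 3.10.9, and correlations were computed with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 under Python 3.11.15.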

Results

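Gene expression was measured by RNA sequencing in MDA-MB-231, described by the submitters as highly metastatic, and in MCF-7, a line of malignant adenocarcinoma that is widely used as a model of estrogen receptor-positive breast cancer. Cells had been cultured with 4sU, a uridine analogue that is built into newly made RNA, for 0, 1, 4 or 8 h. The study was set up to read newly made transcripts through the conversion of 4sU to C in sequencing, and the FPKM table gives 1 value per gene ID and library. The sample titles call the 0 h libraries old and the labelled libraries new. The RNA is labelled as total RNA with poly-T selection in all of them, and whether a selection of newly made RNA entered the labelled libraries was not tested. There was 1 library per line and time. Library totals were 12181782, 12802109, 11108153 and 10046314 reads in MDA-MB-231 at 0, 1, 4 and 8 h, and 12000075, 13758980, 11042580 and 12873181 reads in MCF-7. Between 20748 and 23342 IDs were above 0 in a library, and between 12462 and 13595 reached 1 FPKM.

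The first principal component of the 13899 tested IDs held 65.6% of the variance and separated the lines. The second held 25.6% and separated the 0 h libraries of both lines from the 6 labelled libraries. On the second component MDA-MB-231 lay at -80.4 at 0 h, 2.81 at 1 h, 17.7 at 4 h and 72.6 at 8 h. MCF-7 lay at -103.5 at 0 h, 30.5 at 1 h, 12.5 at 4 h and 47.8 at 8 h, so that its 1 h and 4 h libraries did not follow the order of labelling time.

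**Figure D1:**
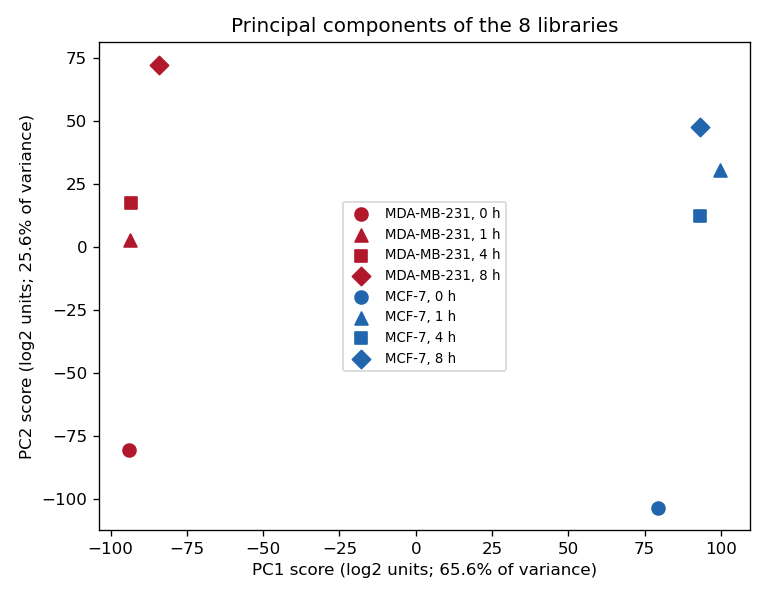
Scores of the 8 libraries on the first and second principal components of log2(FPKM + 1), in log2 units, with colour for the cell line and marker shape for the hours of 4sU labelling. The lines separate along the first component (65.6% of the variance), and the 0 h libraries lie below all labelled libraries along the second (25.6%).

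The first comparison asked which gene IDs differ between the lines. Of 13899 IDs tested, 4148 were higher in MDA-MB-231 and 4430 were higher in MCF-7, together 61.7% of those tested. Among the IDs that passed, the median difference was 1.24 on the log2 scale, with quartiles of 0.829 and 1.94. More than 4-fold differences were found for 859 IDs higher in MDA-MB-231 and 1133 higher in MCF-7. The sign was the same in all 4 time-matched pairs for 67.67% of the IDs tested and for 96.29% of those that passed, a share that the test itself favours.

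Part of the difference between the lines was presence against absence of reads. There were 530 IDs with at least 10 reads in each MCF-7 library and 0 reads in all MDA-MB-231 libraries, and 187 IDs with the opposite pattern. Non-Ensembl IDs made up 127 of the former and 36 of the latter. Of the 482 non-Ensembl IDs tested, 152 were higher in MDA-MB-231 and 205 higher in MCF-7. The Spearman rho across genes between gene length and log2 difference was -0.0138, where genes are not independent replicates.

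The 2 IDs with the largest difference towards MDA-MB-231 on the log2(FPKM + 1) scale were ENSG00000026025 and ENSG00000147065. By the ratio of pooled reads per library total their order reversed, at 707 and 865. The exact 95% counting intervals, 614.7 to 817.6 and 664.2 to 1148, overlap. ENSG00000026025 was at 2081 ± 756 FPKM in MDA-MB-231 and 2.85 ± 2.53 FPKM in MCF-7 (mean ± SD over the 4 times, n = 4), a log2 difference of 9.21 with an SE of 0.20 (limma adjusted p = 1.43e-08). Its FPKM was higher at 8 h than at 0 h in both lines, at 3019 against 1173 in MDA-MB-231 and at 6.52 against 0.851 in MCF-7. ENSG00000147065 was at 729 ± 577 FPKM in MDA-MB-231 and 0.874 ± 0.650 FPKM in MCF-7 (n = 4), a log2 difference of 8.41 with an SE of 0.27 (limma adjusted p = 4.62e-08). Most of its SD in MDA-MB-231 came from the 0 h library, at 1595 FPKM against 451, 443 and 428 FPKM at 1, 4 and 8 h.

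Towards MCF-7 the largest differences on the log2(FPKM + 1) scale were those of ENSG00000235123 and ENSG00000196562. ENSG00000235123 was at 2306 ± 645 FPKM in MCF-7 (n = 4) and had 3 reads in the 4 MDA-MB-231 libraries together. The ratio of pooled reads per library total was 46210, with an exact 95% counting interval of 15810 to 224100. ENSG00000196562 was at 1051 ± 55.2 FPKM in MCF-7 (n = 4) and had 4 reads in the MDA-MB-231 libraries, a ratio of 20950 with a counting interval of 8180 to 76880. On the log2(FPKM + 1) scale the differences were -11.05 with an SE of 0.22 and -9.97 with an SE of 0.17 (limma adjusted p = 1.39e-08 and 7.09e-09).

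The test of the lines was limma's with 4sU time as a factor, and it takes the line difference to be the same at each time. Without the time factor, which leaves the shift between 0 h and labelled libraries in the spread, 5313 IDs passed. Which line held more of the higher IDs was not settled. MDA-MB-231 did without the MCF-7 1 h library (4283 against 4024), the MCF-7 8 h library (3735 against 3662) or the 1 h pair (4219 against 4162). MCF-7 did in the other leave-outs, as without the MDA-MB-231 1 h library (4309 against 4137). With time as a factor, leaving out either library of a pair gives the same line estimates as leaving out both. Such settings differ in the IDs that pass the filter, so they are not separate checks. Without the MCF-7 1 h library 13802 IDs were tested, and without that of MDA-MB-231 13975.

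The second comparison asked which gene IDs differed between the 0 h libraries and those of each time in 4sU. After 1 h, 2034 IDs rose and 2452 fell in the fit over both lines, 32.3% of those tested. After 4 h, 2039 rose and 2427 fell. After 8 h, 3150 rose and 3832 fell, 50.2% of those tested. The excess of falls depended on the scaling: with libraries rescaled by median ratios, 2316 rose and 2259 fell at 1 h, 2304 and 2317 at 4 h, and 3722 and 3410 at 8 h. Without the MDA-MB-231 0 h library, rises also outnumbered falls, at 2321 against 1952, 2333 against 1949 and 3444 against 3386, and without the MDA-MB-231 1 h library they did so at 1 h, at 2650 against 2430. With no filter on low values, falls outnumbered rises by more, with 655 rises and 1436 falls at 1 h and 822 and 1470 at 4 h. As deposited and filtered, 786 of the rises and 920 of the falls at 8 h were more than 4-fold. The median change among the IDs that passed was 1.32 on the log2 scale at 1 h, 1.32 at 4 h and 1.47 at 8 h.

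The changes followed gene length at each time. The tested IDs were divided by length into 5 groups of about equal size. Of the 2787 IDs in the shortest group, up to 946 bases, 1004 rose and 95 fell at 1 h. Of the 2779 IDs in the longest group, from 2377 bases, 52 rose and 1038 fell. At 4 h the shortest group held 1031 rises and 109 falls, and the longest group held 54 rises and 994 falls. At 8 h the shortest group held 1289 rises and 188 falls, and the longest group held 127 rises and 1390 falls. The median length was 952 bases among IDs that rose at 1 h, 2170 bases among those that fell and 1483 bases among those that did not pass. Across genes, the Spearman rho between length and change from 0 h lay between -0.525 and -0.412 in the 6 labelled libraries, with a mean of -0.464. With no filter on low values the mean was -0.252. The 3 values of a line share its 0 h library, so they are not independent, and no second 0 h library was at hand to show the value without a change.

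**Figure D2:**
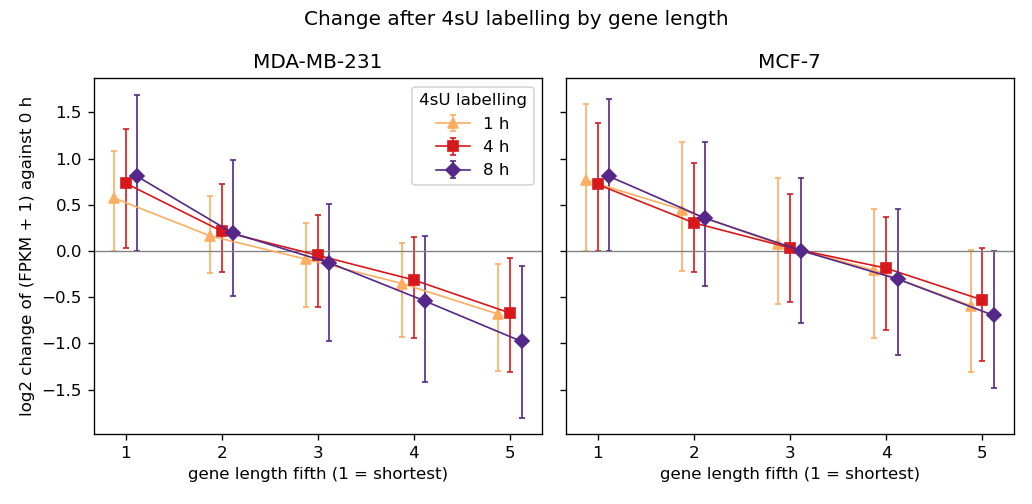
Median log2 change of (FPKM + 1) against the 0 h library of the same line, by gene length group from shortest (1) to longest (5), for each labelling time, with bars from the lower to the upper quartile across genes. In the shortest group the medians lie between 0.57 and 0.81, and in the longest group between -0.98 and -0.53, over both lines.

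The same shift showed in library-wide sums. The mean gene length per read was 1866 bases in MDA-MB-231 and 1851 bases in MCF-7 at 0 h, and between 1393 and 1504 bases in the labelled libraries. The sum of FPKM over all IDs was on average 1.246 times as high in labelled libraries as at 0 h in MDA-MB-231 and 1.195 times as high in MCF-7. The 10 IDs with the highest mean FPKM over all libraries took 3.68% of reads at 0 h and 9.15%, 11.1% and 9.39% at 1, 4 and 8 h in MDA-MB-231. In MCF-7 they took 8.85% at 0 h and 13.6%, 17.0% and 14.1% at those times. Most libraries in that mean were labelled, so the choice of these IDs itself favours a larger share in labelled libraries.

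The changes were shared by the lines, whose libraries are separate at every time. Across genes, the change from 0 h in MDA-MB-231 and that in MCF-7 correlated with a Pearson r of 0.676 at 1 h, 0.768 at 4 h and 0.849 at 8 h (Spearman rho 0.669, 0.771 and 0.851), where genes are not independent replicates. The direction was the same in both lines for 71.31%, 77.11% and 80.95% of tested IDs. After the length trend was removed from each library, r at 1 h was 0.592.

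**Figure D3:**
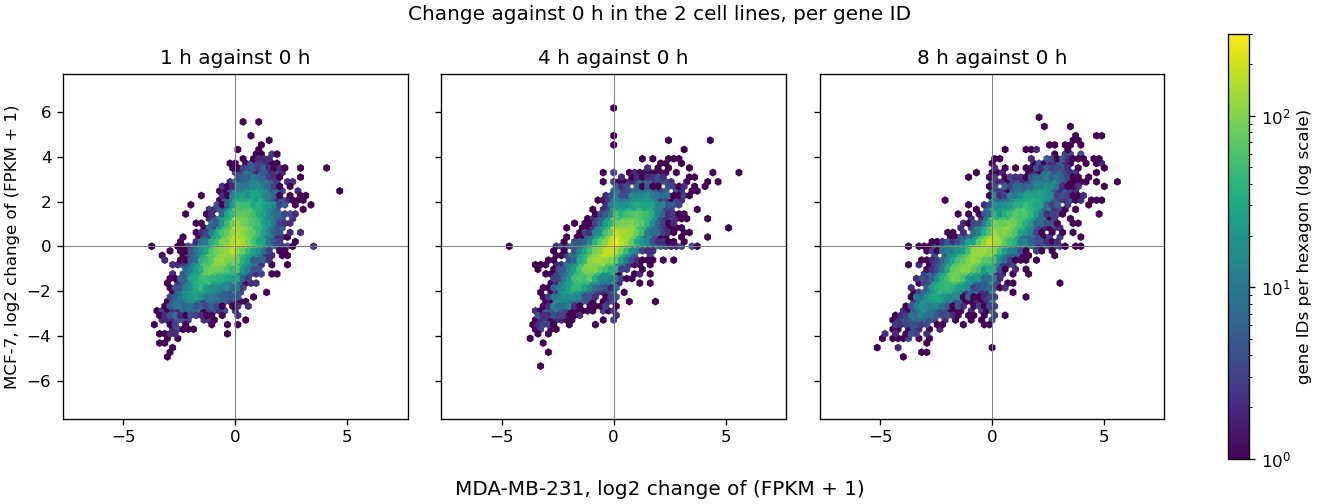
Log2 change of (FPKM + 1) against 0 h in MDA-MB-231 (horizontal) and MCF-7 (vertical) at each labelling time, with each hexagon coloured by the number of gene IDs it holds on a log scale. The clouds lie along the diagonal, with r of 0.676, 0.768 and 0.849 at 1, 4 and 8 h.

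The 2 IDs that rose most at 8 h were ENSG00000229344 and ENSG00000152082. ENSG00000229344, with a length of 682 bases, had 0 reads in both 0 h libraries. It reached 2.63, 18.6 and 30.5 FPKM at 1, 4 and 8 h in MDA-MB-231 and 16.7, 27.9 and 30.3 FPKM in MCF-7. Against a floor of 3 reads per 0 h library it was at least 84.4-fold higher at 8 h in MDA-MB-231 and at least 82.6-fold higher in MCF-7. Whether its reads came from this ID or from a near-identical copy elsewhere was not tested. ENSG00000152082, with a length of 544 bases, went from 13.9 to 42.8, 90.9 and 360 FPKM in MDA-MB-231 and from 10.4 to 303, 176 and 362 FPKM in MCF-7. Its log2 change at 8 h was 4.80 with an SE of 0.62 (limma adjusted p = 0.000436).

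The 2 IDs that fell most at 8 h were ENSG00000067900 and ENSG00000131747. ENSG00000067900, with a length of 2573 bases, went from 155 to 17.8, 18.4 and 3.40 FPKM in MDA-MB-231 and from 169 to 8.81, 13.3 and 5.98 FPKM in MCF-7, a log2 change at 8 h of -4.88 with an SE of 0.37 (limma adjusted p = 0.000155). ENSG00000131747, with a length of 1626 bases, went from 953 to 194, 138 and 30.8 FPKM in MDA-MB-231 and from 392 to 40.6, 37.6 and 20.6 FPKM in MCF-7. Its log2 change was -4.55 with an SE of 0.37 (limma adjusted p = 0.000155).

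Each time was tested with limma with the line as a factor and 2 libraries per time, and both 0 h libraries enter every one of these tests. The count at 4 h rested on both 4 h libraries, with 972 IDs past the threshold without that of MDA-MB-231 and 1122 without that of MCF-7, where the remaining library is assumed to vary like the others. At 1 h, 2609 IDs passed without the MCF-7 1 h library and 2987 without the MCF-7 0 h library. At 8 h, 3447 passed without the MDA-MB-231 8 h library.

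Between labelled times few IDs passed. In the same limma fit, 0 IDs passed for 4 h against 1 h, 0 for 8 h against 1 h and 0 for 8 h against 4 h, with 516, 2171 and 3022 IDs at an unadjusted p under 0.05. Chance alone would give about 0.05 of the 13899 IDs tested, which 2171 and 3022 exceed and 516 does not. Voom on recovered reads called 0, 0 and 5 IDs. These tests were added after the data were examined. With both 0 h libraries left out, limma gave 0, 0 and 3 IDs, with 692, 2680 and 3600 at an unadjusted p under 0.05. Comparisons between labelled times were not simulated. For 8 h against 0 h the simulations recovered 1% of 2-fold and 30% of 4-fold changes. Few IDs past the threshold thus do not show that the labelled times were alike.

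The third comparison asked whether the lines differed in their course over hours of 4sU. In limma's interaction of line and hours, 0 of 13899 IDs passed, 263 had an unadjusted p under 0.05 and voom on recovered reads called 0. The fits of slopes here take a straight line in hours, so a jump from 0 h to 1 h enters their spread. With log2(hours + 1), or without both 0 h libraries, 0 IDs passed too. Without the MCF-7 8 h library 1 ID passed. Of simulated slope differences reaching 4-fold at 8 h in 200 of 13899 genes, 0% were recovered. The recovery with more genes changed, or with the shift from 0 h present, was not simulated. The count of 0 thus neither shows nor excludes differences of that size. Within the lines in the same limma fit, 3 IDs rose in step with hours in MDA-MB-231 and 0 in MCF-7, where 2688 and 1181 had an unadjusted p under 0.05 and voom called 0 in both. A slope common to both lines was called by limma for 0 IDs, with 5015 at an unadjusted p under 0.05, and by voom for 6. The share of tested IDs more than 4-fold from 0 h was 3.40%, 4.92% and 14.6% at 1, 4 and 8 h in MDA-MB-231 and 10.4%, 6.70% and 13.9% in MCF-7, which has no replicate check.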

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

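All tests in this part were chosen after the results were seen. When all labelled libraries were set against 0 h in a limma fit with the interaction of line and labelling, 3 IDs differed between the lines (limma adjusted p = 0.0387 for each, 4 residual degrees of freedom). At an unadjusted p under 0.05 there were 1009, and voom on recovered reads called 0. The 3 are non-Ensembl IDs at 0 in every MDA-MB-231 library, so the difference rests on the MCF-7 0 h library alone against the labelled MCF-7 libraries, and its cause was not tested. The spread comes from the labelled MCF-7 libraries and limma's mean-variance trend, and the MDA-MB-231 values, all 0, lower it. A difference between the lines in their response is therefore not shown. The following 2, the first by size, were chosen after their values were seen. Novel00114 was at 10.2 FPKM in the MCF-7 0 h library and between 0.158 and 0.326 FPKM in the labelled MCF-7 libraries, which put the MDA-MB-231 change minus the MCF-7 change at 3.17 on the log2 scale with an SE of 0.31. Novel01029 was at 9.13 FPKM at 0 h and between 0 and 0.290 FPKM in the labelled MCF-7 libraries, which put the same difference of changes at 3.15 with an SE of 0.33.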

How the results depend on the processing

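The removal of the length trend, the thinning, the voom fits, the trend without both 0 h libraries and the alternatives for the correlations were chosen after the data were examined. The line difference of 8578 IDs became 5592 with a minimum mean of 5 FPKM, which tests fewer genes, 9229, and 5313 without the time factor, all 5313 also past the threshold with it. With no filter, 1 h against 0 h gave 2091 IDs (655 rises, 1436 falls) and 4 h against 0 h gave 2292 (822 and 1470), against 4486 and 4466, with 31779 IDs tested; the cause was not tested. Leaving out 1 library at a time gave between 2609 and 5080 IDs at 1 h, between 972 and 5473 at 4 h, between 3447 and 7583 at 8 h, and 0 or 1 for the trend difference. At 1 h the MCF-7 1 h library (2609 without it) and the MCF-7 0 h library (2987) moved the count by over 1.5 times. At 4 h these were the 4 h libraries of MDA-MB-231 (972) and MCF-7 (1122), at 8 h the MDA-MB-231 8 h library (3447) and for the trend the MCF-7 8 h library (1). A lone sample at a time is assumed to vary like the others. For the lines, leaving out a library or a time-matched pair gave between 6702 and 8464. The other alternatives gave each of the 5 counts within 1.5 times, and the 8 named IDs kept their direction and their side of the threshold in 148 of 148 settings. These IDs were picked as the largest in the same data, and many settings leave their estimates unchanged, so this is a weak check. Without the length trend 3359, 3503 and 6483 IDs passed at 1, 4 and 8 h, of which 2486, 2597 and 4841 were in the main results. Rescaling by median ratios moved the median log2 change of all tested IDs at 8 h from -0.06 to 0.07, and turned the excess of falls into one of rises at 1 h (2316 against 2259) and 8 h (3722 against 3410). Removing the length trend did so at 8 h (3303 against 3180), leaving out the MDA-MB-231 0 h library at 1, 4 and 8 h (2321 against 1952, 2333 against 1949, 3444 against 3386) and leaving out the MDA-MB-231 1 h library at 1 h (2650 against 2430). For the lines the excess towards MCF-7 turned with a minimum mean of 5 FPKM (2920 against 2672) and without the length trend (4429 against 4318). It also turned without the MCF-7 1 h library (4283 against 4024), the MCF-7 8 h library (3735 against 3662) or the 1 h pair (4219 against 4162). Leaving out either library of a pair gives the same line estimates and changes the IDs tested, so these leave-outs are not separate checks. Voom on recovered reads gave 8872 IDs for the lines and 5615, 5539 and 7977 for the times. The mean rho with length was -0.252 with no filter, and 0.0227 once the trend was removed, against -0.464, while the mean correlation between the lines, 0.764, lay between 0.6945 and 0.817. Tests and medians of gene lists were not run, for lack of symbols. Depth limits low genes, at a counting error of 22.15% to 25.92% at 1 FPKM.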

Other observations

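The tests of the share of the length trend, of handling and of the 1 h to 8 h change were chosen after the result was seen, as were the counts of IDs in the first paragraph. At 1 h, 233 IDs were more than 4-fold below 0 h on the log2(FPKM + 1) scale in both lines, 1.68% of those tested, with a median length of 2450 bases. Another 28 were more than 4-fold above 0 h in both, with a median length of 490 bases. If all libraries hold the whole mRNA, a 4-fold fall within 1 h needs a half-life of at most 30 min even where transcription stops at once. FPKM is a share of each library, so this also takes the total mRNA and its recovery as reads to be unchanged, which was not tested. With at least 10 reads in both 0 h libraries and 0 in all labelled ones there were 3 IDs, and 2 IDs had the opposite pattern.

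The shift between the 0 h and the labelled libraries was already present at 1 h. Library depth as its cause is argued against by the totals at 0 h, 12181782 and 12000075 reads, which lie inside the labelled range of 10046314 to 13758980. Thinning to one total, a small step here, gave 4418 IDs at 1 h. A change in proportion to the hours of labelling is argued against too: the 1 h to 8 h change of one line would have a slope of about 7 on the 0 h to 1 h change of the other, and the larger of the 2 slopes was 0.433. The gene length trend, at a mean rho of -0.464 over 6 labelled libraries that share 2 at 0 h, may be part of the shift. The average trend, as fitted on the recovered length, was not the whole. Without it 3359 IDs passed at 1 h, 2486 of them also passing with it. Departures of single genes from this average stay in the values, so a cause linked to length is not excluded for the whole shift. Handling given only to labelled RNA, including any selection of new RNA, and a rapid response of both lines to 4sU cannot be told apart. Each predicts the correlation of 0.676 between the lines at 1 h. The labels do not say whether the 0 h RNA was handled as the labelled RNA was. These need not be the only causes left, since the aligner is not given and how reads with 4sU-to-C conversions were aligned was not tested.

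The 8 h libraries lay farther from 0 h than the 1 h libraries. The 1 h to 8 h changes of the lines, which share no library, correlated across genes at 0.335, and at 0.326 after the length trend was removed, which is consistent with a component common to both lines at 8 h. For the 1 h to 4 h changes the correlation was only 0.0952, so a steady course common to both lines was not seen up to 4 h. In MDA-MB-231 the 1 h to 8 h change also followed the 0 h to 1 h change of MCF-7, with r of 0.645, so there it may be more of the same shift. In MCF-7 this was not so, with r of 0.161 against the 0 h to 1 h change of MDA-MB-231. The slope across genes of the MCF-7 change from 0 h on the MDA-MB-231 8 h change was 0.746, 0.635 and 0.842 at 1, 4 and 8 h. That of MDA-MB-231 on the MCF-7 8 h change was 0.439, 0.517 and 0.857. The MCF-7 1 h library thus already lay far along the shift, and the low r may rest on it. A biological time course stays open, with 1 library per line and time.

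For the line difference, 1 of the 32 splits of the 8 libraries that could be fitted gave as many genes, the real one with 8578, and the highest other split gave 0. These splits exchange libraries across times; those that keep the time-matched pairs number only 8, with 0 in the highest other, too few for a share under 0.05. A further 3 splits coincide with the time factor and could not be fitted. For the trend difference, with 0 genes, 35 of 35 splits gave as many, which a count of 0 fixes in advance, so this decides nothing. The highest other gave 2530. That split and the next, with 2004, exchange the lines between early and late times, so the line difference enters their time trend.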
